A study of Homo sapiens with 6 samples.

How the data were processed

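The series compared 2 groups of MCF12A cells, with 3 samples each of cells stably over-expressing miR-424 and of cells with the empty vector (EV). Total RNA was taken after 48 hours and Illumina libraries were made with a kit for mRNA, per the labels' protocols. Nothing in the labels says whether the 3 samples of a group came from independently derived lines or separate experiments, so p-values measure only the spread between these samples, which may be technical. The labels call the line a breast cancer line; MCF12A is otherwise known as an immortalized, non-tumorigenic mammary epithelial line. Groups and replicate numbers were taken from the sample titles, and the columns of the table were matched to samples by title.

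The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments) with 1 column per sample and the position of each locus. TopHat 1.4.1, Cufflinks 1.3.0 and Cuffdiff and the builds hg19 and GRCh37 are named in the submitters' processing notes, which give no role or order for them. The gene annotation, the number of reads, the denominator of the FPKM values and any scaling between libraries are not given in the sources used here. FPKM values do not give the fragment counts from which counting error is estimated, so no test of counts was used and no interval or limit of detection is given. Low FPKM values were compared between libraries for steps of whole fragments, which gave relative depths between 0.77 and 1.22 of EV replicate 1. Only 4.0% to 11.4% of the low loci lay within 0.03 (log2) of the step used, so these depths are approximate.

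The table held 24294 loci, of which 4952 were at 0 in all libraries and 643 had a blank symbol. Another 28 symbols had been turned into dates and were recovered through their RefSeq transcripts. The 1187 loci on haplotype or unplaced sequences were all listed at 0. A locus can be a merged bundle: 286 tested loci carry several symbols, whose genes share 1 value, and 96 carry a symbol that is listed more than once. Use of strand is not given in the sources used here, so overlapping genes on opposite strands may share reads, and values of near-identical paralogs are uncertain. Small RNAs shorter than a sequenced fragment have unstable FPKM values.

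Values were transformed to log2(FPKM + 1) and loci with a mean of at least 1 FPKM over the 6 samples were tested (11574 loci). Fold changes are on this scale and understate the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3, with a trended prior variance, no covariate and no further scaling, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 3 against 3 samples cannot go below a p of 0.1, so it was not used for single genes. Gene lists, 31 in all, were tested where at least 5 members were tested (27 lists) with camera, a competitive test with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Each list was also tested with an estimated correlation and with fry, which tests whether a list moves one way and does not compare it with other genes. Of the 27 lists, 19 passed with the preset correlation and 0 with the estimated one. Members are also counted with p adjusted over the list alone.

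The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were reported targets of miR-424 and of microRNAs with its seed, epithelial identity, junctions, mesenchymal genes, transcription factors of epithelial-mesenchymal transition, ERK output, TGF-beta and BMP components, TGF-beta response, G1/S, G2/M, basal mammary, luminal mammary, stem and tumour-initiating cells, squamous differentiation, integrins, basement membrane, EGF family, Notch, interferon, NF-kB and cytokines, p53 targets, hypoxia and glycolysis, cholesterol synthesis, ATF4 and ER stress, serum response and YAP, fibroblasts, leukocytes, endothelial cells, mitochondrially encoded transcripts, ribosomal proteins and core histones. Named genes were (a) MIR424, MIR503, MIR503HG, TWIST1, TGFBR3, CDH1, VIM, CDH2 and FN1; (b) the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap and whose higher group mean was at least 5 FPKM; and (c) for each list up to 4 members past the threshold with the smallest adjusted p, or where none passed the 2 with the highest mean. Some genes that this rule selects are not reported here. Further members are named only where a count is small, and MIR4750, TNC, PMEPA1 and KRT14 were so named after their values were seen. MIR503HG is the symbol that later annotation gives to MGC16121.

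Sequences of 3' UTRs were taken from GENCODE 29, a GRCh38 annotation, by gene symbol or RefSeq transcript and never by coordinate. Of the tested loci 11104 (95.9%) matched a GENCODE gene and 10437 had an annotated 3' UTR of at least 30 nt; coordinates in the text are hg19, as in the table. The longest 3' UTR of each gene was searched for TGCTGCT and GCTGCTA. Loci with and without a match were paired on 3' UTR length and GC content within 0.1 SD. GC and length trends of each library were removed with lowess (span 0.3). Heptamer ranks were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

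The procedure was tested on simulated data for the miR-424 against EV comparison, with 200 of 11574 loci changed. With libraries of like spread, 35.8%, 89.6% and 97.0% of changes of 0.3, 0.6 and 1.2 (log2) were recovered, with 11 false among 159 calls. With miR-424 replicate 3 as spread as observed the shares were 38.8%, 83.6% and 98.5%, with 2 false among 149 calls. The simulated noise was independent between loci, and that of replicate 3 had 1 SD for all loci and no GC trend. In the setting of like spread, the residuals of replicate 3 entered the spread of every library. The simulations therefore do not give the error rate or power of the real comparison. Alternatives covered the pseudocount (0.1 and 0.5), the minimum of FPKM (none and 5), median-of-ratios scaling, quantile normalization, the prior variance, the replicate number as a block, each library left out in turn, a stricter threshold, the list test and the definition of the seed match. Removing GC or length trends, limma array weights, transcripts of at least 300 nt and median-of-ratios scaling for the seed match were added after the data were seen.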

Results

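Gene expression was measured by RNA sequencing in MCF12A cells, an immortalized human mammary epithelial line, that carried either a stable miR-424 construct or the empty vector (EV). Each of the 2 groups held 3 samples, harvested after 48 hours of growth. Each library is represented by 1 FPKM value for each of 24294 loci, and FPKM values summed to between 409776 and 424564 per library. Read numbers were not given in the sources used here. Steps in the low FPKM values gave only approximate depths relative to EV replicate 1, of 1.04 and 0.96 for EV replicates 2 and 3 and of 0.84, 0.77 and 1.22 for miR-424 replicates 1, 2 and 3. The comparison asked which transcripts differ when miR-424, a microRNA that the study's title places downstream of the transcription factor TWIST1, is over-expressed.

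The construct was read out first. The locus listed as MGC16121/MIR424, the host transcript of the microRNA at chromosome X, 133677406 to 133680741 (hg19), was at 1.16 ± 0.15 FPKM in EV cells and 145 ± 67.6 FPKM in miR-424 cells (SD, n = 3 each). The 3 miR-424 libraries read 107, 106 and 224 FPKM, so that each lay far above the EV libraries, and the log2 change was 5.99 ± 0.28 (SE; limma, Benjamini-Hochberg adjusted p = 0.000668). MIR503, annotated within the same locus, was listed at 0 in 2 libraries of each group and at 0.643 FPKM in EV replicate 3 and 0.612 FPKM in miR-424 replicate 3. These values come from an mRNA library and do not measure the mature microRNAs.

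Most differences between miR-424 and EV cells were small. Fibronectin (FN1; chromosome 2, 216225178 to 216300791) rose from 265 ± 2.35 to 421 ± 5.84 FPKM and keratin 5 (KRT5) fell from 63.7 ± 2.27 to 40.7 ± 3.22 FPKM (SD, n = 3). Of 11574 loci with a mean of at least 1 FPKM, 144 were higher and 731 were lower in miR-424 cells at a Benjamini-Hochberg adjusted p under 0.05 (limma). The median absolute log2 change of these loci was 0.30, and 32 of the rises and 62 of the falls reached an absolute log2 change of 0.5. On the log2(FPKM + 1) scale, an absolute log2 change of 1 was reached by 2 rises, MGC16121/MIR424 and LYPD6B, and by 3 falls, CXCR4, SNORD4A and MIR4750. This scale understates the change of low loci. By the ratio of mean FPKM, miR-424 over EV, further loci changed by more than a factor of 2. Examples were SLC16A6 (2.20), SULF1 (2.20), CDKN1C (0.461) and MMP28 (0.473). MIR4750, named after its values were seen, was listed at 0 in all 3 miR-424 libraries and at 4.02, 7.15 and 3.67 FPKM in EV replicates 1, 2 and 3.

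The balance of rises and falls depended on the scaling between libraries and the number of loci depended on which libraries were included. Median-of-ratios scaling gave 308 rises and 495 falls, so that 38.4% of the loci past the threshold were rises against 16.5% with the values as deposited, and quantile normalization gave 319 and 447 (41.6%). The median absolute log2 difference per locus was 0.0408 between miR-424 replicates 1 and 2. Between replicate 3 and each of them it was 0.142 and 0.152. The signed median difference of replicate 3 from replicates 1 and 2 was -0.0912 and -0.0902, so replicate 3 lay lower over loci as a whole. Medians of gene lists in single libraries, given below, are not corrected for this shift. Leaving out miR-424 replicate 3 gave 1728 rises and 2574 falls, which included all 875 loci. Replicates 1 and 2, left in that comparison, shared a trend on transcript GC content against EV. Their median deviations were 0.065 and 0.082 under 40% GC and -0.093 and -0.120 over 60%. Replicate 3 had a trend the other way, from -0.215 to -0.051. Leaving it out was not combined with removal of the GC trend. The calls gained without replicate 3, also in the lists below, can therefore not be told apart from that trend. Leaving out EV replicate 1, 2 or 3 gave 34 and 77, 31 and 79, and 35 and 84, and leaving out miR-424 replicate 1 or 2 gave 63 and 280, and 83 and 365.

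Among the 12 largest rises that met the selection rule, LYPD6B, a member of the Ly6/uPAR family, went from 3.74 ± 0.10 to 9.64 ± 0.67 FPKM (log2 change 1.17 ± 0.06, SE; chromosome 2, 149894980 to 150071772). SLC16A6, of the monocarboxylate transporter family, rose by 0.97 ± 0.06 and SULF1, which removes sulfate groups from heparan sulfate, by 0.91 ± 0.05 on the log2 scale. Adhesion and matrix genes in this group were AMIGO2 (21.3 ± 0.60 to 41.0 ± 4.03 FPKM), the collagen gene COL8A1 (log2 change 0.86) and SEMA7A (0.78). F3, which encodes tissue factor, rose from 101 ± 1.80 to 171 ± 19.9 FPKM, the chromatin protein gene HMGA2 from 39.5 ± 0.39 to 66.7 ± 8.88 FPKM and DUSP6, a phosphatase of ERK, from 12.8 ± 0.23 to 21.9 ± 1.54 FPKM (SD, n = 3). WDR69 (0.73) and MIR221 (0.89) completed the group. MIR221 is shorter than a sequenced fragment, which makes its FPKM unstable, and it lost the call when EV replicate 1, 2 or 3 was left out, with limma Benjamini-Hochberg adjusted p = 0.108, 0.0703 and 0.105. Leaving out EV replicate 1, 2 or 3 also ended the call of HMGA2 (adjusted p = 0.0588, 0.0571 and 0.0558, limma with Benjamini-Hochberg adjustment), and leaving out EV replicate 1 that of F3 (0.0522).

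CXCR4, the receptor of the chemokine CXCL12, had the most negative log2 change of the falls in the selected group, from 11.2 ± 0.55 to 4.27 ± 0.24 FPKM (log2 change -1.22 ± 0.06, SE; chromosome 2, 136871918 to 136875725). MMP28, a secreted metalloproteinase, fell by 0.95, LY6D by 0.89, and the cyclin-dependent kinase inhibitor gene CDKN1C by 0.89 on the log2 scale. SMPD1, which encodes acid sphingomyelinase, fell from 7.15 ± 0.11 to 3.54 ± 0.19 FPKM and the transcription factor gene TFCP2L1 from 8.96 ± 0.27 to 4.70 ± 0.27 FPKM (SD, n = 3). MAMDC2, CRABP2 (a retinoic acid binding protein), PPP1R14C and METTL7A had log2 changes of -0.77, -0.73, -0.73 and -0.72. The locus ARL2/SNX15, in which a pair of neighbouring genes share a value, fell from 31.3 ± 1.29 to 18.2 ± 0.99 FPKM. SNORD4A, a small nucleolar RNA shorter than a fragment, had a log2 change of -1.17 ± 0.26 (SE; limma, Benjamini-Hochberg adjusted p = 0.0437) and passed in 11 of 17 alternative settings. The call of CDKN1C ended without EV replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.0588 and 0.0578) and that of METTL7A without EV replicate 1, 2 or 3 (0.0588, 0.0531 and 0.0556). For the 23 other loci of these groups of 12, the adjusted p from limma (Benjamini-Hochberg) lay between 0.000668 and 0.0237.

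**Figure D1:**
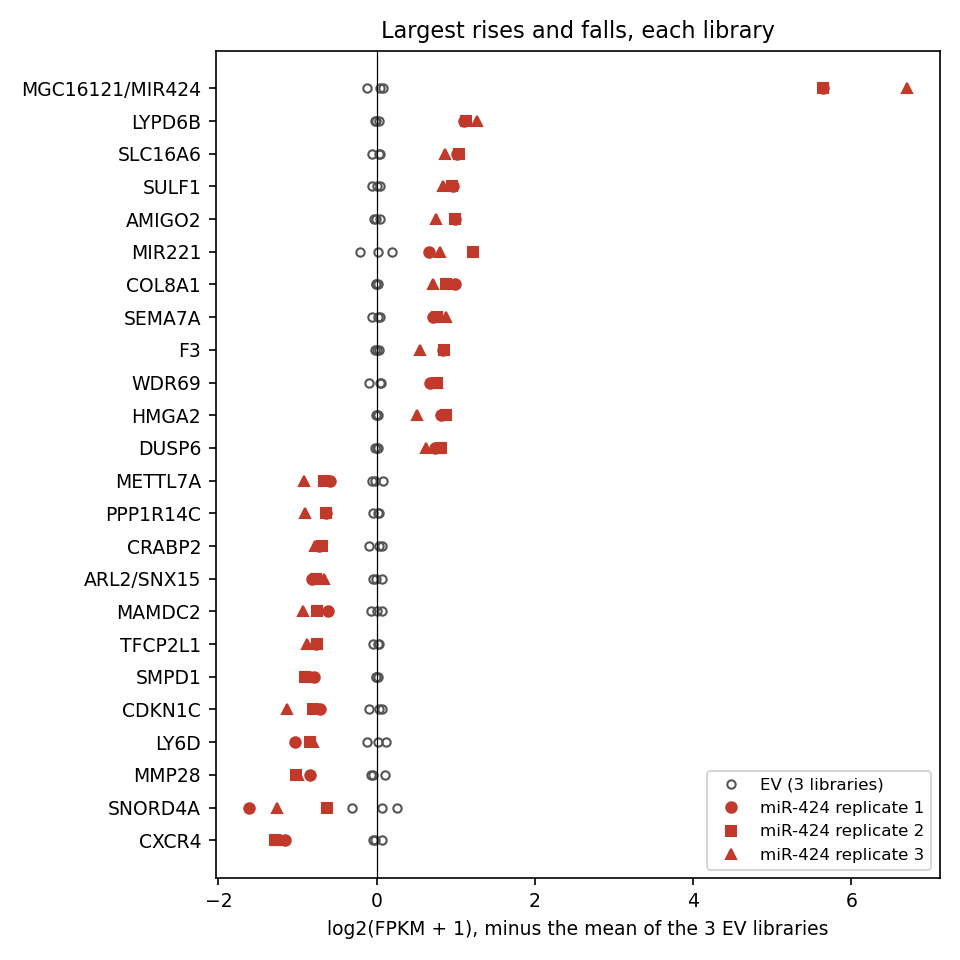
Values of each library on the log2(FPKM + 1) scale, minus the mean of the 3 EV libraries, for the 12 largest rises and 12 largest falls that met the selection rule (open circles, EV; filled symbols, miR-424). For each locus the 3 miR-424 libraries lie on the same side of the 3 EV libraries.

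Mesenchymal genes rose more often than they fell. Of 26 tested members of a list of mesenchymal cytoskeleton, matrix and adhesion genes, 7 rose and 1, the matrix protein gene TNC, fell, and 9 rose and 2 fell when adjusted over the list alone. FN1 (log2 change 0.67 ± 0.03, SE), the actin-binding protein gene TAGLN (6.72 ± 0.77 to 10.6 ± 0.49 FPKM, SD, n = 3), COL6A3 (0.33 ± 0.05) and MMP2 (66.5 ± 1.15 to 78.1 ± 2.44 FPKM) had the smallest adjusted p. Vimentin (VIM, 970 ± 14.2 FPKM in EV cells, log2 change 0.04 ± 0.04) and N-cadherin (CDH2, 27.4 ± 0.81 FPKM in EV cells, log2 change 0.03 ± 0.05) did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.588 and 0.784). Camera placed the list above other genes (Benjamini-Hochberg adjusted p = 1.86e-07), which gave adjusted p = 0.101 with an estimated correlation. The median change of the list against the EV mean was 0.15 and 0.14 in miR-424 replicates 1 and 2 and 0.02 in replicate 3. These medians are not corrected for the lower level of replicate 3 over loci as a whole (-0.0912 and -0.0902 against replicates 1 and 2). Leaving out miR-424 replicate 3 gave 15 and 2, and leaving out any 1 of the other 5 libraries (EV replicates 1 to 3 and miR-424 replicates 1 and 2) gave 1 to 4 and 0.

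Junction genes that passed the test fell, as did most loci past the threshold (731 of 875). Of 14 tested genes of tight junctions and desmosomes 7 fell and 0 rose, and 11 fell and 1 rose when adjusted over the list alone. The desmosomal linker gene periplakin (PPL) fell from 2.34 ± 0.16 to 1.42 ± 0.07 FPKM, claudin 7 (CLDN7) from 2.03 ± 0.02 to 1.36 ± 0.11 FPKM, plakophilin 3 (PKP3) from 6.23 ± 0.20 to 5.01 ± 0.07 FPKM and desmoglein 3 (DSG3) from 1.22 ± 0.04 to 0.841 ± 0.050 FPKM (SD, n = 3). By camera the list differed from other genes (Benjamini-Hochberg adjusted p = 0.000288), with adjusted p = 0.101 with an estimated correlation. With quantile normalization DSG3 did not pass (limma, Benjamini-Hochberg adjusted p = 0.0532). PKP3 did not pass with the GC trend or with GC and length trends removed (limma, Benjamini-Hochberg adjusted p = 0.0840 and 0.0919), where 9 members fell. Without miR-424 replicate 3, 11 members fell and 1 rose, and without any 1 of the other 5 libraries 1 to 4 fell. E-cadherin (CDH1; chromosome 16, 68771194 to 68869444) was at 0.0228 ± 0.0142 FPKM in EV and 0.0183 ± 0.0038 FPKM in miR-424 cells, under the minimum for testing. Of 24 epithelial identity genes 5 were tested, 1 fell, also when adjusted over the list alone, and the list as a group did not pass (camera, Benjamini-Hochberg adjusted p = 0.445). In this list 0 fell without any 1 library other than miR-424 replicate 3, and 2 fell without that one.

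Of 12 tested transcription factors linked to epithelial-mesenchymal transition, 0 passed the limma test, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. TWIST1 (chromosome 7, 19155090 to 19157295) was at 60.3 ± 2.22 FPKM in EV cells and 46.2 ± 11.5 FPKM in miR-424 cells (limma, Benjamini-Hochberg adjusted p = 0.220), with 52.4, 53.2 and 32.9 FPKM in miR-424 replicates 1, 2 and 3. SNAI2 was at 53.4 ± 1.24 and 51.5 ± 5.24 FPKM. The median log2 change of the list was -0.03 and its mean -0.05, whereas camera, which compares the list with other genes, gave the direction up (Benjamini-Hochberg adjusted p = 0.539). The median was 0.02 with median-of-ratios scaling and 0.04 with quantile normalization. There were 4 rises and 4 falls without miR-424 replicate 3, TWIST1 among the falls with a log2 change of -0.19 (limma, Benjamini-Hochberg adjusted p = 0.00466, in a range of 0.00466 to 0.484 over 18 alternatives).

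Basal mammary markers that passed the test moved in both directions. KRT5 (log2 change -0.63 ± 0.06, SE), the integrin subunit gene ITGB4 (14.9 ± 0.40 to 10.4 ± 0.69 FPKM) and TRIM29 (1.45 ± 0.06 to 0.592 ± 0.069 FPKM, SD, n = 3) were among 4 basal markers that fell, while 2 rose, of 15 tested. The rises included KRT14 (2.25 ± 0.24 to 4.36 ± 0.80 FPKM), named after its values were seen. The counts were the same when adjusted over the list alone. Basal falls and rises without miR-424 replicate 3 were 5 and 4, and without any 1 of the other 5 libraries 2 to 3 and 1 to 2. The median and mean log2 changes (-0.03 and -0.05) differed in sign from camera, which gave up with a Benjamini-Hochberg adjusted p of 0.604, and fry gave down (Benjamini-Hochberg adjusted p = 0.00635). The median was 0.02 with median-of-ratios scaling and with quantile normalization. Of 8 tested luminal markers 1 fell, the protease inhibitor gene SLPI (14.8 ± 0.61 to 11.1 ± 0.74 FPKM), and 3 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.206, and fry 0.0182, down). Of 11 tested markers of mammary stem and tumour-initiating cells 1 rose, the integrin subunit gene ITGB3 (2.13 ± 0.09 to 3.27 ± 0.17 FPKM), and 1 rose and 4 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.546). Of 5 tested squamous genes 1 fell, the alarmin gene S100A8 (3.86 ± 0.45 to 1.79 ± 0.26 FPKM), and 2 fell when adjusted over the list alone. Camera placed the squamous list below other genes (Benjamini-Hochberg adjusted p = 0.0234, 0.0652 without miR-424 replicate 2 and 0.520 without a filter on low values), with adjusted p = 0.255 with an estimated correlation. Leaving out miR-424 replicate 3 gave 1 rise and 4 falls for luminal, 3 and 4 for stem cell and 0 and 2 for squamous genes. The luminal fall was lost without EV replicate 1, 2 or 3, the stem cell rise without EV replicate 2 and the squamous fall without EV replicate 1. There were 2 luminal falls without miR-424 replicate 1.

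Among 14 tested integrin subunits, ITGB3 and ITGB8 (7.69 ± 0.27 to 11.6 ± 1.71 FPKM) rose and ITGB4 fell, with the same counts when adjusted over the list alone. Of these subunits 8 rose and 2 fell without miR-424 replicate 3, 1 and 0, 0 and 1, and 1 and 0 without EV replicate 1, 2 and 3, and 1 and 1 without miR-424 replicate 1 or 2. As a list they differed from other genes (camera, Benjamini-Hochberg adjusted p = 0.000241), with adjusted p = 0.101 with an estimated correlation. Basement membrane genes were split, with 5 rises and 3 falls among 18 tested members and 7 and 4 when adjusted over the list alone. Laminin alpha 4 (LAMA4) rose from 7.50 ± 0.02 to 12.9 ± 0.14 FPKM and nidogen 2 (NID2) by 0.30 ± 0.05 on the log2 scale (SE), while laminin alpha 5, in the locus LAMA5/MIR4758, fell from 6.96 ± 0.25 to 4.34 ± 0.32 FPKM (SD, n = 3). The median log2 change of this list was -0.02, its mean 0.04 and the camera direction up (Benjamini-Hochberg adjusted p = 0.0174), with adjusted p = 0.255 with an estimated correlation. The median became 0.04 with median-of-ratios scaling and 0.02 with quantile normalization, and camera no longer passed (Benjamini-Hochberg adjusted p = 0.0948 and 0.182), nor without miR-424 replicate 3 (0.328). There were then 7 rises and 7 falls, against 2 to 3 and 1 to 2 without any 1 of the other 5 libraries.

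Growth factor and kinase output genes included rises of pathway inhibitors. Of 19 tested genes that follow ERK activity 5 rose and 1 fell, also when adjusted over the list alone. The rises included DUSP6, SPRY4 (2.78 ± 0.01 to 3.86 ± 0.28 FPKM) and SPRY2 (24.9 ± 0.42 to 29.4 ± 0.28 FPKM), which encode feedback inhibitors of the pathway, and the fall was CCND1, which encodes cyclin D1 and is also in the list of reported miR-424 targets. For the list, camera gave a Benjamini-Hochberg adjusted p of 0.000803, and adjusted p = 0.408 with an estimated correlation. Its median change against the EV mean was 0.08 in miR-424 replicates 1 and 2 and -0.04 in replicate 3. Of 8 tested EGF family genes the ligands EREG (3.14 ± 0.17 to 4.93 ± 0.30 FPKM) and TGFA (10.6 ± 0.16 to 12.4 ± 0.53 FPKM) rose and the receptor ERBB2 fell (8.73 ± 0.24 to 7.16 ± 0.04 FPKM, SD, n = 3), and 5 rose and 1 fell when adjusted over the list alone. Camera gave a Benjamini-Hochberg adjusted p of 0.000803 for this list, and adjusted p = 0.101 with an estimated correlation; it no longer passed without a filter on low values (0.0532) or at a minimum of 5 FPKM (0.0553). The ERK list without miR-424 replicate 3 had 7 rises and 3 falls and the EGF list 5 and 1, and without any 1 of the other 5 libraries the rises were 1 to 2 and 1 and the falls 0 to 1 and 0. The fall of ERBB2 ended in each of these 5 (limma, Benjamini-Hochberg adjusted p from 0.0512 to 0.0964).

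In the TGF-beta system, the ligand and receptor genes were split. Of 26 tested TGF-beta and BMP components 5 rose and 3 fell, and 7 rose and 4 fell when adjusted over the list alone. BMP2 (2.96 ± 0.20 to 5.27 ± 0.45 FPKM) and the latent TGF-beta binding proteins LTBP1 (log2 change 0.28 ± 0.03, SE) and LTBP2 (0.33 ± 0.04) rose, and TGFB1 fell from 31.3 ± 0.44 to 23.1 ± 1.58 FPKM. TGFBR3, the co-receptor betaglycan (chromosome 1, 92145899 to 92371559), fell from 2.16 ± 0.07 to 1.5 ± 0.20 FPKM (SD, n = 3; log2 change -0.34 ± 0.07, SE; limma, Benjamini-Hochberg adjusted p = 0.0312), and passed in 11 of 17 alternatives. Its adjusted p was 0.142, 0.116 and 0.139 without EV replicate 1, 2 and 3 and 0.0738 without miR-424 replicate 1 (limma, Benjamini-Hochberg). The median log2 change of the list was -0.002, its mean 0.06 and the camera direction up (Benjamini-Hochberg adjusted p = 0.00770), with adjusted p = 0.507 with an estimated correlation. That median was 0.05 with median-of-ratios scaling and with quantile normalization. Of 13 tested TGF-beta response genes 4 rose and 1, PMEPA1, fell, and 4 rose and 2 fell when adjusted over the list alone. TGFBI, an extracellular matrix protein, rose from 353 ± 8.42 to 489 ± 20.6 FPKM and tropomyosin 1 (TPM1) from 38.7 ± 0.48 to 51.6 ± 1.49 FPKM. By camera the list differed from other genes (Benjamini-Hochberg adjusted p = 0.000931), with adjusted p = 0.408 with an estimated correlation. Its median change against the EV mean was 0.12 and 0.11 in miR-424 replicates 1 and 2 and -0.004 in replicate 3. Of 16 serum response and YAP target genes 3 rose (TAGLN, TPM1 and CYR61, at 86.2 ± 2.27 and 116 ± 2.40 FPKM) and 5 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.56e-06), with adjusted p = 0.101 with an estimated correlation. Without miR-424 replicate 3 the rises and falls were 11 and 5 for components, 6 and 2 for response genes and 9 and 2 for serum response genes. Leaving out EV replicate 1, 2 or 3 gave 1 and 0, 1 and 0, and 2 and 0 for components. For response genes it gave 2 and 0, 3 and 0, and 3 and 0, and for serum response genes 2, 3 and 3 rises with 0 falls. Leaving out miR-424 replicate 1 or 2 gave 3 and 1, and 3 and 2 for components, 4 and 0, and 4 and 1 for response genes and 3 rises with 0 falls for serum response genes.

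Cell cycle genes that passed the test fell, as did 731 of all 875 loci past the threshold. Of 31 tested G1/S and DNA replication genes 5 fell and 0 rose, and 11 fell when adjusted over the list alone. Cyclin E1 (CCNE1) fell from 10.5 ± 0.23 to 7.53 ± 0.20 FPKM, E2F2 from 3.31 ± 0.09 to 2.52 ± 0.07 FPKM, the phosphatase gene CDC25A from 9.40 ± 0.20 to 7.33 ± 0.61 FPKM and GINS1 from 19.3 ± 0.25 to 16.4 ± 0.73 FPKM (SD, n = 3). As a list they differed from other genes (camera, Benjamini-Hochberg adjusted p = 0.000104), with adjusted p = 0.185 with an estimated correlation. Of 33 tested G2/M genes 5 fell, and 8 when adjusted over the list alone, among them the kinesin genes KIF20A (-0.17 ± 0.03) and KIF23 (-0.17 ± 0.04), UBE2C (-0.23 ± 0.05) and BIRC5, which encodes survivin (-0.28 ± 0.06; log2 changes with SE). With median-of-ratios scaling and quantile normalization 3 G2/M genes fell, and KIF20A (limma, Benjamini-Hochberg adjusted p = 0.165 and 0.110) and KIF23 (0.102 and 0.0768) did not pass. Leaving out any 1 library other than miR-424 replicate 3 ended the calls of KIF20A, KIF23, UBE2C and BIRC5. For the list, camera gave a Benjamini-Hochberg adjusted p of 0.000335, and adjusted p = 0.448 with an estimated correlation. Fry gave this list a Benjamini-Hochberg adjusted p of 0.0704. The median change of the G2/M list against the EV mean was -0.09 in miR-424 replicate 1, -0.10 in replicate 2 and -0.36 in replicate 3. In the G1/S and G2/M lists there were 21 and 20 falls, with 1 rise in each, without miR-424 replicate 3, and without any 1 of the other 5 libraries 1 to 3 and 0.

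Stress-related genes that passed the test also fell, as did most loci past the threshold (731 of 875). Of 21 p53 target genes 6 fell and 0 rose, and 7 fell when adjusted over the list alone, including TP53I3 (8.31 ± 0.43 to 5.14 ± 0.23 FPKM), FDXR (28.8 ± 1.14 to 22.1 ± 1.01 FPKM), the cyclin-dependent kinase inhibitor gene CDKN1A (322 ± 0.62 to 282 ± 4.98 FPKM) and SESN2 (7.75 ± 0.29 to 5.86 ± 0.44 FPKM, SD, n = 3). Camera gave a Benjamini-Hochberg adjusted p of 0.0174 for this list, and adjusted p = 0.432 with an estimated correlation. Its median change against the EV mean was -0.09 and -0.12 in miR-424 replicates 1 and 2 and -0.26 in replicate 3. Of 17 tested ATF4 and endoplasmic reticulum stress genes 7 fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone. They included DDIT4 (297 ± 1.11 to 243 ± 3.17 FPKM), DDIT3, which encodes CHOP (9.43 ± 0.12 to 6.99 ± 0.29 FPKM), the serine synthesis gene PHGDH (3.01 ± 0.06 to 2.10 ± 0.11 FPKM) and the amino acid transporter gene SLC7A5 (156 ± 2.03 to 125 ± 7.89 FPKM). By camera the list differed from other genes (Benjamini-Hochberg adjusted p = 0.0199), with adjusted p = 0.185 with an estimated correlation. Of 9 tested Notch pathway genes the ligand genes JAG1 (9.60 ± 0.30 to 7.49 ± 0.14 FPKM) and DLL3 (1.65 ± 0.06 to 1.27 ± 0.09 FPKM) fell, and 3 when adjusted over the list alone. As a list they differed from other genes (camera, Benjamini-Hochberg adjusted p = 0.0130), with adjusted p = 0.188 with an estimated correlation. Without miR-424 replicate 3, 9 p53 targets fell and 2 rose, 9 stress genes fell and 2 rose, and 7 Notch genes fell, while the stress list no longer passed camera (Benjamini-Hochberg adjusted p = 0.0632), nor did it at a minimum of 5 FPKM (0.0825), with the GC trend removed (0.0596) or with GC and length trends removed (0.0939). Leaving out any 1 EV library gave 1 fall of p53 targets, 0 of stress genes and 0 of Notch genes. Leaving out miR-424 replicate 1 or 2 gave 3 and 3, 4 and 5, and 1 and 1, with no rise in these lists. With median-of-ratios scaling and quantile normalization DLL3 (limma, Benjamini-Hochberg adjusted p = 0.105 and 0.174) and SLC7A5 (0.0931 and 0.0522) did not pass, nor did CDKN1A with median-of-ratios scaling (0.174).

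Metabolic and inflammatory lists held few members past the threshold. Of 21 hypoxia and glycolysis genes VEGFA (22.4 ± 0.84 to 32.7 ± 2.69 FPKM), the vascular endothelial growth factor, and hexokinase 2 (HK2, 6.0 ± 0.20 to 7.89 ± 0.27 FPKM) rose, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.81e-06), with adjusted p = 0.101 with an estimated correlation. Of 24 cholesterol synthesis genes 1 rose, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00290), with adjusted p = 0.270 with an estimated correlation. Of 15 tested NF-kB target and cytokine genes LIF and IL6 rose (log2 changes 0.39 ± 0.05 and 0.25 ± 0.06, SE) and BIRC3 and SOD2 fell (-0.37 ± 0.05 and -0.29 ± 0.06), and 5 rose and 4 fell when adjusted over the list alone. For the list, camera gave a Benjamini-Hochberg adjusted p of 0.0312, and adjusted p = 0.454 with an estimated correlation. Of 11 tested interferon-stimulated genes IFI44L rose (0.40 ± 0.08) and OAS3 and IFI6 fell (-0.55 ± 0.06 and -0.42 ± 0.08), with 2 and 2 when adjusted over the list alone. The median and mean log2 changes (-0.05 and -0.06) differed in sign from camera, which gave up (Benjamini-Hochberg adjusted p = 0.879). IFI6 did not pass with quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0548). Without miR-424 replicate 3 the rises and falls were 11 and 1 for hypoxia, 8 and 2 for cholesterol synthesis, 6 and 4 for NF-kB and 3 and 2 for interferon genes. Leaving out EV replicate 1, 2 or 3 gave 0 rises and 0 falls for hypoxia and cholesterol synthesis, 0 and 0, 1 and 0, and 0 and 0 for NF-kB and 0 and 1 for interferon genes. Leaving out miR-424 replicate 1 or 2 gave 2 and 0 for hypoxia, 0 and 0, and 1 and 0 for cholesterol synthesis, 1 and 1 for NF-kB and 0 and 1 for interferon genes. The NF-kB list no longer passed camera without miR-424 replicate 2 or 3 (Benjamini-Hochberg adjusted p = 0.120 and 0.187) or with median-of-ratios or quantile scaling (0.218 and 0.220).

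Markers of other cell types and of RNA quality were read in the same way. Of 12 fibroblast markers 4 were tested, of which COL1A1 (39.0 ± 1.49 to 45.2 ± 1.66 FPKM) and COL6A3 rose, with 3 rises when adjusted over the list alone 4 without miR-424 replicate 3, 0 without any 1 EV library and 1 without miR-424 replicate 1 or 2. Both are also in the mesenchymal list. Of 13 leukocyte markers 3 were tested and 0 passed (limma), also when adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 2 falls without miR-424 replicate 3; CD68 was at 55.9 ± 1.53 and 54.7 ± 3.28 FPKM and LAPTM5 at 29.4 ± 1.02 and 26.5 ± 1.38 FPKM. Of 10 endothelial markers 0 reached the minimum for testing, and the highest mean was 0.213 FPKM. Of 57 ribosomal protein genes 0 passed (limma), also when adjusted over the list alone, with 4 at an unadjusted p under 0.05; RPS18 and RPS2 had log2 changes of 0.06 ± 0.07 and -0.07 ± 0.09 (SE). Their median change against the EV mean was -0.04 and -0.06 in miR-424 replicates 1 and 2 and 0.05 in replicate 3, and leaving out replicate 3 gave 3 rises and 16 falls. The list's median and mean log2 changes (-0.02 for both) differed in sign from camera, which gave up (Benjamini-Hochberg adjusted p = 0.171), and the median was 0.04 with median-of-ratios scaling and 0.01 with quantile normalization. It passed camera as up without EV replicate 1 (0.0495), miR-424 replicate 1 (0.0162) or miR-424 replicate 2 (0.00265), or with GC and length trends removed (0.0127). Without miR-424 replicate 3 it passed as down (0.0168). Of 6 tested replication-dependent histone genes HIST1H1C fell (26.9 ± 1.22 to 18.6 ± 2.48 FPKM, SD, n = 3), and 1 rose and 1 fell when adjusted over the list alone, with a median of 0.003, a mean of -0.06 and a camera direction of up (Benjamini-Hochberg adjusted p = 0.426). Histone calls were 0 rises and 0 falls without any 1 EV library or miR-424 replicate 2, 0 and 1 without miR-424 replicate 1 and 1 and 1 without miR-424 replicate 3. Transcripts of the mitochondrial genome were not analysed here.

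**Figure D2:**
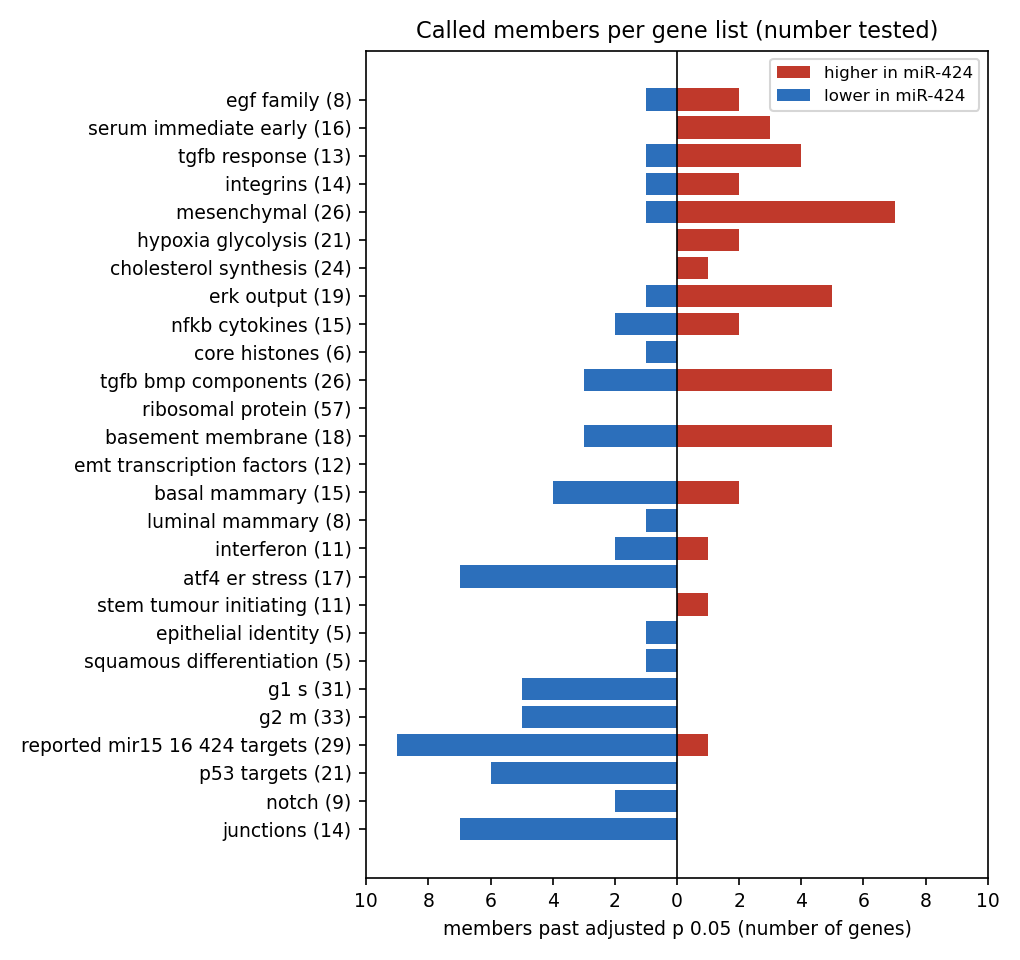
Number of genes of each list that were higher (right) or lower (left) in miR-424 than in EV cells at an adjusted p under 0.05, with the number of members tested in brackets, for the 27 lists with at least 5 members tested. The mesenchymal list has 7 members higher and 1 lower, and the junction list has 0 higher and 7 lower.

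Of 29 tested genes reported in the literature as direct targets of miR-424-5p or of microRNAs with the same seed, 9 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. CCNE1 (log2 change -0.43 ± 0.04), CCND1 (82.3 ± 1.5 to 64.6 ± 1.28 FPKM), the cyclin D3 gene CCND3 (82.9 ± 2.39 to 66.7 ± 1.19 FPKM, SD, n = 3) and the locus ARL2/SNX15 had the smallest adjusted p, and the rise was VEGFA. Camera gave a Benjamini-Hochberg adjusted p of 0.00777 for this list, and adjusted p = 0.507 with an estimated correlation. Its median change against the EV mean was -0.11 and -0.09 in miR-424 replicates 1 and 2 and -0.28 in replicate 3. Without miR-424 replicate 3, 14 fell and 4 rose, and without any 1 of the other 5 libraries 2 to 7 fell.

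The transcriptome was then divided by the presence of a miR-424-5p seed match. The mature sequence used was CAGCAGCAATTCATGTTTTGAA (written as DNA), whose positions 2 to 8 pair with TGCTGCT, and the 8mer match is TGCTGCTA. Of 10437 tested loci with an annotated 3' UTR, 2991 held a match (TGCTGCT or GCTGCTA) and had a median log2 change of -0.06, against -0.04 for the 7446 loci without. The difference of medians was -0.0209 (camera p = 0.0511, and p = 0.655 with an estimated correlation), which did not pass. With an estimated correlation p was 0.03 under median-of-ratios scaling and 0.0472 under quantile normalization (camera), where the differences were -0.0219 and -0.0165. In 2516 pairs of loci matched on 3' UTR length and GC content it was -0.0327 (camera p = 0.00309, and p = 0.486 with an estimated correlation). For the 510 loci with an 8mer match it was -0.0314 (camera p = 0.00697, and p = 0.646 with an estimated correlation). The 8mer loci were set against the 9927 loci without an 8mer match, some of which held TGCTGCT or GCTGCTA. Median log2 changes were -0.0574, -0.0641, -0.0736 and -0.0855 for 1, 2, 3 and 4 or more matches. Against the EV mean, the difference was -0.0160, -0.0134 and -0.0346 in miR-424 replicates 1, 2 and 3, and between each EV library and the other EV libraries it was -0.00633, 0.00600 and 0.00145. Among loci that fell, 285 of 680 with an annotated 3' UTR held a match (41.9%), as did 34 of 137 that rose (24.8%) and 2672 of 9620 that passed in neither direction (27.8%). Genes with a match were found among the falls (SMPD1, TFCP2L1, PPP1R14C and MAMDC2) and among the rises (HMGA2, SLC16A6 and COL8A1).

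**Figure D3:**
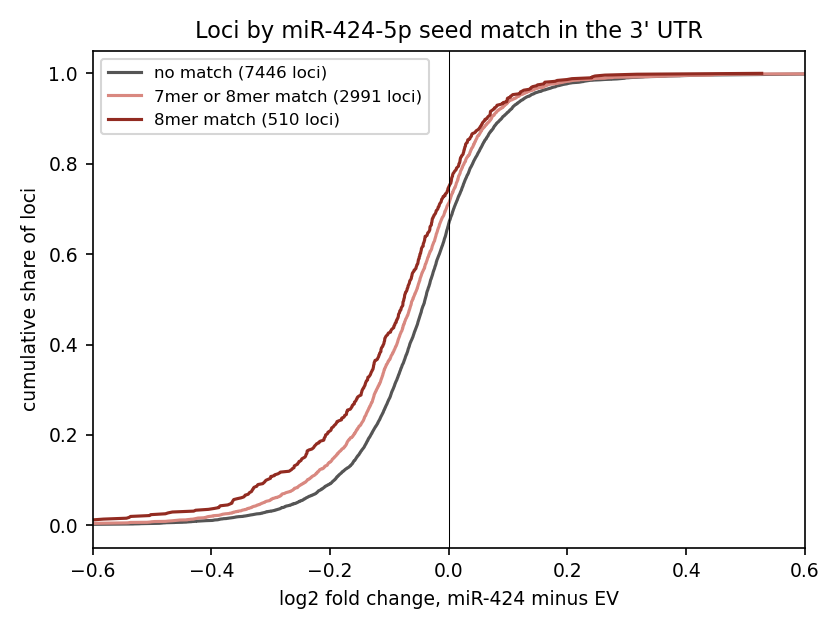
Cumulative share of loci (vertical axis) by log2 change in miR-424 against EV cells (horizontal axis) for 7446 loci without a miR-424-5p seed match in the 3' UTR, 2991 with a match and 510 with an 8mer match. The medians are -0.04, -0.06 and -0.08.

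When each heptamer was scored by the difference of medians between loci with and without it in the 3' UTR, TGCTGCT ranked 165 from the lowest of 15707 heptamers held by at least 100 loci. After the trend of log2 change on 3' UTR length and GC content was removed it ranked 17, and GCTGCTA, the match to positions 2 to 7 followed by A, ranked 1 with a difference of -0.0339. The lowest heptamer before this step was GCGCGGG (-0.0517). With the trend left in, the rank of TGCTGCT was 181, 209 and 85 without EV replicate 1, 2 and 3, and 61, 19 and 1668 without miR-424 replicate 1, 2 and 3. Leaving out a library was not combined with removal of the trend. For miR-424 replicates 1, 2 and 3, each against the EV mean, it ranked 1037, 1890 and 4542 with the trend left in. After the trend was removed these ranks were 11, 16 and 177. Genes are not independent replicates, so these ranks describe these libraries only.

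**Figure D4:**
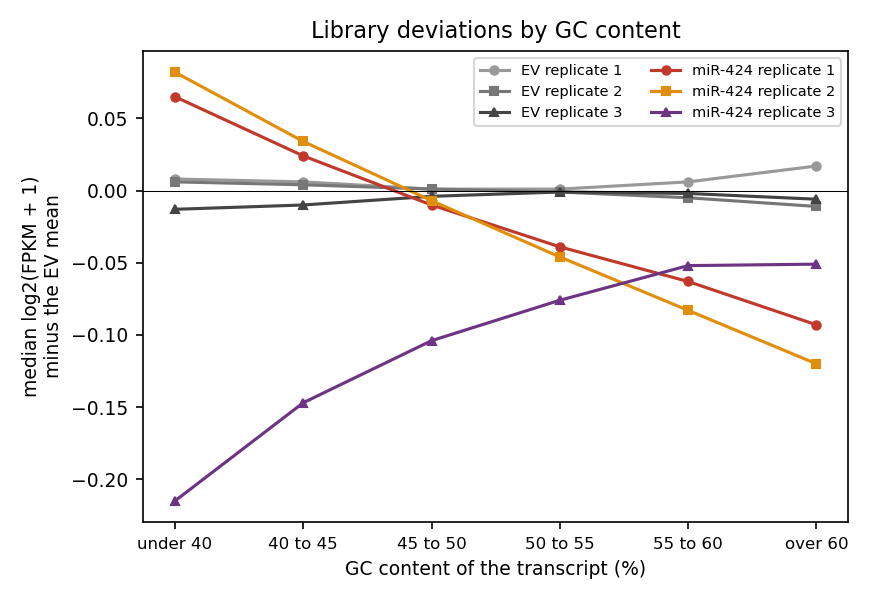
Median log2(FPKM + 1) of each library minus the EV mean, by GC content of the transcript. From under 40% to over 60% GC, miR-424 replicates 1 and 2 go from 0.065 and 0.082 to -0.093 and -0.120 and miR-424 replicate 3 from -0.215 to -0.051, while the EV libraries stay between -0.013 and 0.017.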

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

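Removal of GC and length trends, array weights, transcripts of at least 300 nt and median-of-ratios scaling of the seed-match result were chosen only after the data were seen. No locus of the 875 changed sign under any alternative, but many lost the call. Of the 875, 601 also passed with median-of-ratios scaling, 557 with quantile normalization and 705 with GC and length trends removed. For 97 named loci, 1452 of 1716 values lay on the same side of the threshold. Without EV replicate 1, 2 and 3 the call ended for 54, 51 and 50 of these 97.

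Rises and falls numbered 308 and 495 with median-of-ratios scaling, 319 and 447 with quantile normalization, 107 and 468 at a minimum of 5 FPKM (fewer loci tested), 50 and 155 at an adjusted p under 0.01 (limma, Benjamini-Hochberg) and 2 and 3 with an absolute log2 change of 1. They were 265 and 923 without the GC trend, 279 and 926 without GC and length trends, and 1256 and 2307 with array weights. Removal of GC and length trends ended the calls of 7 named loci (PKP3, DLL3, SLPI, FDXR, UBE2C, BIRC5 and HIST1H1C). Removal of the GC trend alone ended those of PKP3 and DLL3. With 1 library left out rises ranged from 31 to 1728 and falls from 77 to 2574: 34 and 77, 31 and 79, and 35 and 84 without EV replicate 1, 2 and 3, and 63 and 280, 83 and 365, and 1728 and 2574 without miR-424 replicate 1, 2 and 3. Beyond fewer samples or loci, the cause was not tested.

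With the replicate number as a block there were 79 rises and 270 falls. Deviations of same-numbered samples correlated at 0.051, 0.152 and 0.127. EV replicates 2 and 3 correlated best with the same-numbered miR-424 library, but EV replicate 1 with miR-424 replicate 2 (0.061). These values do not settle whether the samples were paired, and the main test took no pairing. The block left the log2 changes as they were, so the seed-match difference (-0.0209) and the rank of TGCTGCT (165) stayed the same. No list changed its camera call, but 23 named loci lost theirs. Falls went from 5 to 1 for G1/S and from 5 to 0 for G2/M genes.

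Camera placed 11 lists above and 8 below other genes, and 0 and 0 with an estimated correlation (6 of 27 at an unadjusted p under 0.05). The median log2 change over all tested loci was -0.0466, so a list above other genes need not have risen. Fry, which does not compare a list with other genes, gave 6 up and 10 down. With 1 library left out, the lists above and below by camera ranged from 9 to 12 and from 7 to 8. Where either value passed, opposite directions were given by basal markers under fry (median -0.0349, against camera's up; fry, Benjamini-Hochberg adjusted p = 0.00635), NF-kB genes at a minimum of 5 FPKM (-0.0971; camera, Benjamini-Hochberg adjusted p = 0.432) and ribosomal proteins without miR-424 replicate 3 (-0.0398; camera, Benjamini-Hochberg adjusted p = 0.0168; medians from -0.0398 to 0.00817 with 1 library left out). Fry also gave down against camera's up, with neither passing, for transcription factors of epithelial-mesenchymal transition, interferon genes, ribosomal proteins and histones (fry, Benjamini-Hochberg adjusted p = 0.694, 0.138, 0.611 and 0.694). Calls lost with fry were ERK output, TGF-beta and BMP components, TGF-beta response, G2/M, NF-kB and cholesterol synthesis (fry, Benjamini-Hochberg adjusted p = 0.141, 0.516, 0.0536, 0.0704, 0.611 and 0.354), and those gained were epithelial identity, basal (down) and luminal (0.00357, 0.00635 and 0.0182). Because only camera compares with other genes, a list with small falls can be up by camera and down by fry. The cause of the other differences was not tested.

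The seed-match difference passed at a minimum of 5 FPKM (-0.0229), with median-of-ratios scaling (-0.0219), without the GC trend (-0.0233) or GC and length trends (-0.0290), for 8mers (-0.0314), shortest 3' UTRs (-0.0305) and matched loci (-0.0327), with camera p between 0.00210 and 0.0465. It did not pass with quantile normalization (-0.0165) or array weights (-0.0136). With an estimated correlation camera gave p = 0.03 with median-of-ratios scaling and 0.0472 with quantile normalization, 0.592 at a minimum of 5 FPKM, 0.594 and 0.503 without the GC trend and without GC and length trends, 0.646 for 8mers, 0.504 for shortest 3' UTRs, 0.486 for matched loci and 0.627 with array weights. With 1 library left out the difference ranged from -0.0232 to -0.0116: -0.0206 (passed), -0.0186 and -0.0222 without EV replicate 1, 2 and 3, and -0.0218 (passed), -0.0232 (passed) and -0.0116 without miR-424 replicate 1, 2 and 3. With an estimated correlation none of these 6 passed (camera p = 0.649, 0.700 and 0.684 without EV replicate 1, 2 and 3, and 0.616, 0.659 and 0.256 without miR-424 replicate 1, 2 and 3). The cause was not tested.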

Other observations

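Tests of GC content and length, of scaling between libraries and of other splits of the samples were chosen after the result was seen; the other tests below were set before theirs.

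The EV cells had high levels of some mesenchymal transcripts and low levels of others alongside keratins, and the genes named here and in the next paragraph beyond the selection rule were chosen after their values were seen. VIM was at 970 ± 14.2 FPKM, DCN, which encodes the proteoglycan decorin, at 120 ± 4.13, MMP2 at 66.5 ± 1.15, TWIST1 at 60.3 ± 2.22, SNAI2 at 53.4 ± 1.24 and CDH2 at 27.4 ± 0.81 FPKM (SD, n = 3). Other mesenchymal or fibroblast markers were low: SPARC at 0.267 ± 0.056, LUM at 0.0503 ± 0.0404, COL1A2 at 0.0148 ± 0.0078, THY1 at 0.0657 ± 0.0154, PDGFRA at 0.0226 ± 0.0105 and the locus COL3A1/MIR3606 at 0.555 ± 0.040 FPKM. KRT8 was at 164 ± 4.27, KRT18 at 88.1 ± 2.99 and KRT5 at 63.7 ± 2.27 FPKM, and the claudin gene CLDN4 at 21.3 ± 0.18 FPKM. CDH1 (0.0228 ± 0.0142 FPKM) and the splicing regulator gene ESRP1 (0.256 ± 0.032 FPKM) were under the minimum for testing, the transcription factor gene GRHL2 was listed at 0 in all 6 libraries, and the basal regulator gene TP63 was at 0.133 ± 0.036 FPKM. EPCAM was at 2.60 ± 0.09 FPKM in EV and 2.84 ± 0.34 FPKM in miR-424 cells (limma, Benjamini-Hochberg adjusted p = 0.491). A decrease of CDH1 could therefore not be read in these libraries, and FN1 was the transcript of the selected mesenchymal markers VIM, CDH2 and FN1 that passed the test.

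Replicate 3 of miR-424 lay apart from replicates 1 and 2, with a robust spread (MAD) against their mean that was 3.23 times the spread between them. Its deviations followed transcript GC content across loci (Spearman rho 0.623), but after GC and length trends were removed the ratio was still 2.38, which argues against such bias as the whole cause although the MAD itself dropped from 0.195 to 0.136. Lower depth is argued against by a ratio of 5.42 among 3635 loci of at least 20 FPKM, and RNA from fibroblasts, leukocytes or endothelial cells by a largest median marker difference of 0, to which members near 0 FPKM contribute, and by levels in replicate 3, against replicates 1 and 2, of 0.181 against 0.166 and 0.206 FPKM for LUM, 0.0498 against 0.0679 and 0.0637 FPKM for PTPRC and 0.166 against 0.181 and 0.224 FPKM for PECAM1, although CD68 (58.5 against 52.7 and 52.9 FPKM), LAPTM5 (28.1 against 25.8 and 25.7 FPKM) and LYZ (1.29 against 1.06 and 1.22 FPKM) were higher; other cell types were not tested. A stronger response stays open. Changes were 0.777 times as large as in replicate 2 over 203 loci, with 62.1% smaller in replicate 3 (exact binomial p = 0.000716). The share was 58% with quantile normalization (exact binomial p = 0.0341) and 56.6% with median-of-ratios scaling (exact binomial p = 0.0739). But these loci were picked on replicate 1, which shares its GC trend with replicate 2. After GC and length trends were removed the ratio was 0.911, with 52.7% of 186 loci smaller in replicate 3 (exact binomial p = 0.509). The binomial test takes loci as independent and sets 1 library against 1 library. Its p-values therefore do not measure a difference between cultures. In replicate 3 reported targets were at -0.28 against -0.11 and -0.09 and the construct locus at 224 FPKM against 107 and 106 FPKM. But replicate 3 lay lower over loci as a whole (median log2 difference -0.0912 and -0.0902 from replicates 1 and 2). G2/M genes were also lower there, at -0.36 against -0.09 and -0.10. The seed-match difference was larger in replicate 3 over all loci (-0.0346 against -0.0160 and -0.0134). In matched loci it was smaller (-0.0282 against -0.0391 and -0.0388). These values do not settle whether the response was stronger. A difference in culture state or library preparation of that sample may also remain; neither was tested.

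Falls outnumbered rises 731 to 144. Quantile normalization raised the share of rises by 25.1 percentage points, but equalizing the distributions moves the median of all loci (by 0.0524) by construction, so this does not show whether scaling between libraries or a real excess of falls lies behind the balance, and scaling stays open. Seed matches were 1.507 times as frequent among falls as among loci that passed in neither direction, which is consistent with repression by miR-424-5p for some of them. Of the falls with an annotated 3' UTR, 58.1% had no match.

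The median log2 change was lower by 0.0209 for loci with a miR-424-5p seed match than for loci without, which did not pass the test (camera p = 0.0511, and 0.655 with an estimated correlation). Matching on 3' UTR length and GC content gave a difference of -0.0327, below 0 in each miR-424 library (-0.0391, -0.0388 and -0.0282), which argues against those properties as the cause. After the trend on both was removed, 0.108% of heptamers had a difference as low as that of TGCTGCT, which argues against a property of any frequent heptamer. A hypothesis that stays open is weak, widespread repression through the seed, but camera with an estimated correlation gave p = 0.486 for the matched loci and, unmatched, 0.03 with median-of-ratios scaling and 0.0472 with quantile normalization, and the unmatched difference without miR-424 replicate 3 was -0.0116 (camera p = 0.187). These patterns were found and tested on the same libraries.

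Of the 10 splits of the 6 samples into groups of 3, 1 (the real one) gave 875 loci past the threshold and the highest of the others gave 3; 10 splits are too few for a share under 0.05. Between groups, 33.5% of tested loci did not overlap (3876 loci), against 10% by chance for 3 against 3. That 10% assumes no shift of whole libraries between groups, and the median log2 change over all tested loci was -0.0466. Such a shift raises the share without a change of single genes, so the excess does not show how many loci changed.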
